A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

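Gene expression was measured in stationary phase cells of the budding yeast Saccharomyces cerevisiae on 5 one-colour Agilent arrays labelled with Cy3. There were 2 arrays of the wild type BY4741, a laboratory strain of mating type a, and 1 array each of strains with RAD50, MRE11 or XRS2 deleted. The labels number the wild type arrays 1 and 2, and do not say whether these came from separate cultures. All 5 arrays lay on 1 slide and were read in 1 scan.

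Per the file headers, each array was quantified with Agilent Feature Extraction 10.7.3.1, with spatial detrending and with replacement values for signals not above noise. The deposited scanner files give signals as a linear intensity per spot, not normalized between arrays. Their other columns used here are flags of 0 or 1 for spot quality, saturation and signal well above background, which the deposited files hold as other values with no unit. The authors also deposited processed log2 values, 1 per gene, which the file's header describes as a shift to the 75th percentile in GeneSpring GX. The authors' values followed the scanner values across genes with r = 0.9999 on 4 arrays and r = 0.996 on the rad50 deletion array. Probe positions are those the files give, on build sacCer1. A reference gene table of assembly R64 served only for names and for the order of neighbouring genes, and 5738 of the 6227 genes on the array matched it by locus tag.

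Control spots and spots with an outlier mark were removed. The processed signal was put on the log2 scale and the array's 75th percentile was subtracted, so that every level below is a log2 signal relative to that percentile. Spots were averaged to probes (6256 probes with 2 to 3 spots each) and probes to genes. More than 1 probe was present for 28 genes, and the probes differed by over 1 on the log2 scale in 0 of them. A gene was tested if it was well above background on at least 1 array, which left 6152 genes. Of these, 5792 were well above background on all 5 arrays. Another 65 genes were above background on no array and 10 had no usable spots on at least 1 array. The array annotates 523 of the tested genes as dubious open reading frames.

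The 75th percentile of the signal was 2500 and 2244 intensity units in wild type replicates 1 and 2, 1506 in the rad50 deletion, 1740 in the mre11 deletion and 2371 in the xrs2 deletion. The share of genes well above background was 95.9%, 98.7%, 93.3%, 97.2% and 98.4% in the same order. Replicate spots of a probe differed by a typical SD of 0.03 to 0.05 on the log2 scale. The number of arrays limits the precision.

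Tests were run with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The first fit compared the 3 deletion strains, taken as 1 arm, with the 2 wild type arrays. It had 3 residual degrees of freedom, and its spread held the differences between strains. The second fit had 4 groups and gave each strain against wild type and each pair of strains. It had 1 residual degree of freedom, from the wild type pair, and each lone deletion array was assumed to vary like the wild type arrays. The adjusted p-values measure spread between samples that may be technical. Where a gene was not above background on one side of a comparison, the fold is given as a bound against the dimmest signal well above background on the arrays of that side, or against the gene's own signal where that was higher.

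Before the data were examined, 45 gene lists were fixed, of which 43 had at least 3 measured members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. For each strain alone, a list's median was set against 10000 random lists of the same size matched on signal in 20 bins. Lists were compared between strains with camera on the 4-group fit at the preset correlation, adjusted over all lists and pairs. After the results were seen, camera on the plain log2 differences at the preset correlation was also run for the wild type pair and the pairs of strains, adjusted over the lists within each pair.

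The rule for naming genes was also fixed then. For the strains together it took the 10 largest rises and falls past the threshold among genes above background on all 5 arrays with every deletion beyond both wild type arrays. For each strain it took the 6 largest rises and falls that passed and lay beyond both wild type arrays by at least 1 on the log2 scale, and for each pair of strains the 3 largest differences each way. It added the deleted genes, strain markers, mating type genes, the largest bounds and up to 4 members of each described list.

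Alternatives tried were normexp background correction with an offset of 50, quantile normalization, median centring, a filter for genes above background on all 5 arrays, no such filter, the authors' table, the brightest probe per gene, a spread with a trend on signal, the spread of the other fit, other thresholds, and leaving out each array in turn. Cyclic loess and a count without dubious reading frames were added after the data were seen.

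The procedure was tested on simulated data with 6152 genes of which 200 were changed. In the comparison of the 3 deletions with wild type it recovered 95% of the 2-fold changes and 98% of the 4-fold changes, with 10 false calls among 203. In the 4-group fit it recovered 100% of both sizes for each strain against wild type. False calls there were 22 of 222 for the rad50 deletion, 17 of 217 for mre11 and 37 of 237 for xrs2. For pairs of strains they were 22 of 222 for rad50 and mre11, 51 of 251 for rad50 and xrs2 and 14 of 212 for mre11 and xrs2, with 98% to 100% recovered. The false share of the 4-group fit was thus above the 5% that its threshold allows. All simulated arrays had the same noise for a gene, so this does not test a lone deletion array that varies more than wild type. With 1 list shifted by 0.5 on the log2 scale, 1 list passed. The simulated noise was independent between genes, so this does not test list calls where genes vary together. In the data the estimated correlation was, for example, 0.81 within the ribosome biogenesis list and -0.025 within the list of DNA damage-induced genes.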

Results

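RNA levels were measured in stationary phase yeast grown in synthetic minimal medium with dextrose, in 2 wild type samples and in 1 sample each of strains lacking RAD50, MRE11 or XRS2. These genes encode the subunits of the MRX complex, which binds the ends of DNA double-strand breaks. There were no replicates within a deletion strain. The wild type arrays correlated with r = 0.996 across genes, which are not independent replicates, and their log2 difference had an SD of 0.22 over genes. Every other pair of arrays had an SD between 0.32 and 0.46. Of the genes tested, 30 differed at least 2-fold between the wild type arrays, and 6 of those were well above background on all arrays.

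On each deletion array the strain's own deleted gene was not above background. RAD50 (YNL250W, probe on chromosome XIV from 179290 to 179349) stood at -0.59 in both wild type arrays and was at least 104-fold lower in the rad50 deletion, with an adjusted p of 2.5e-05. It stood at -0.84 in the mre11 deletion and at -1.01 in the xrs2 deletion. MRE11 (YMR224C, chromosome XIII from 718671 to 718730) had wild type levels of -3.37 and -3.36 and was at least 28.7-fold lower in the mre11 deletion, with an adjusted p of 7.9e-05. XRS2 (YDR369C, chromosome IV from 1215205 to 1215264) had wild type levels of -3.39 and -3.42 and was at least 38.9-fold lower in the xrs2 deletion, with an adjusted p of 4.6e-05. The markers HIS3, LEU2, MET17 and URA3, which BY4741 lacks in whole or in part, were not above background on any array, and LYS2, which it retains, had a mean of -1.42 in wild type and -1.41 in the deletions. Of the 6 genes next to the deleted ones, 0 passed in the 3 deletions together, over all genes tested, and 1 passed adjusted over the list alone. NRD1, beside RAD50, had the largest difference of them at 0.94 (adjusted p = 0.108). In the single strains NRD1 stood at 0.84 in the rad50 deletion itself, with an adjusted p of 0.0975, and rose by 1.37 in the mre11 deletion, with an adjusted p of 0.031. YPR1, beside XRS2, fell by 0.80 in the xrs2 deletion itself, with an adjusted p of 0.0497.

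**Figure D1:**
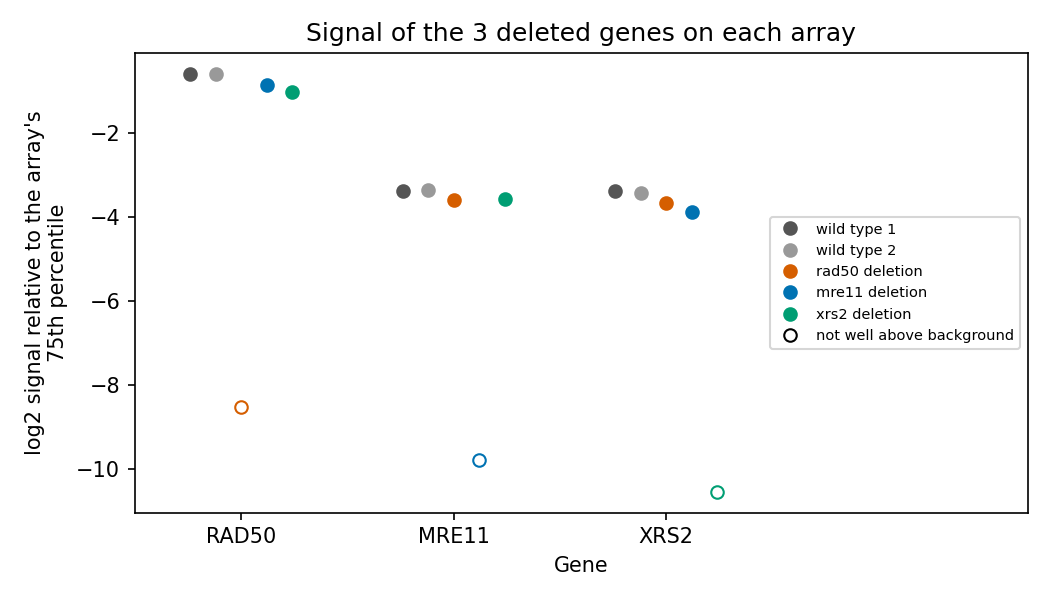
Log2 signal of RAD50, MRE11 and XRS2 relative to the 75th percentile of each array (y axis), with 1 point per array. Open points were not well above background, and each lies in the strain in which that gene was deleted, as for RAD50 at -8.51 against -0.59 in wild type.

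The comparison of the 3 deletions with wild type asks which RNA levels change when the MRX complex is lost. The largest rise was that of COS12, a member of a family of membrane protein genes near chromosome ends, which rose 19.2-fold. YGL262W, the next measured gene on that end of chromosome VII, rose 12.6-fold, and HUG1, which is induced by DNA damage and replication stress, rose 9.18-fold. Other genes that rose included the G1 cyclin gene CLN2, the mitotic cyclin gene CLB2 and RNR1, for the large subunit of ribonucleotide reductase, an enzyme of DNA precursor synthesis. Falls were fewer and smaller, and the largest was a 2.23-fold fall of YHR022C. In all, 226 of 6152 genes passed, of which 212 rose and 14 fell, and 1150 genes had an unadjusted p under 0.05.

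COS12 (YGL263W, chromosome VII from 3656 to 3715) rose by 4.26 ± 0.20 (SE) on the log2 scale, with an adjusted p of 4.4e-04. Its level was -7.07 ± 0.39 (SD, n = 2) in wild type and -2.81 ± 0.20 (SD, n = 3) in the deletions. YGL262W (chromosome VII from 5585 to 5644) rose by 3.66 ± 0.15, from -6.38 ± 0.05 to -2.72 ± 0.22, with an adjusted p of 2.2e-04. HUG1 (YML058W-A, chromosome XIII from 158787 to 158846) rose by 3.20 ± 0.12, from -5.86 ± 0.03 to -2.66 ± 0.15, with an adjusted p of 2.2e-04. WSC2 (YNL283C, chromosome XIV from 105244 to 105303), a sensor of cell wall stress, rose by 2.40 ± 0.15. TOS4 (YLR183C, chromosome XII from 520569 to 520628), a target of the G1/S transcription factor SBF, rose by 2.23 ± 0.14. HXT4, a glucose transporter gene, rose by 2.27 ± 0.19, the cell wall protein gene CIS3 by 2.15 ± 0.20 and YNL058C by 2.05 ± 0.15. YAR075W rose by 2.40 and IMD2, for an enzyme of guanine nucleotide synthesis, by 2.03, but the pair belongs to a near-identical family, so which copy changed is uncertain. These 7 genes had adjusted p-values between 0.00133 and 0.00661. YLR012C was not above background in wild type and was at least 5.61-fold higher in the deletions, with an adjusted p of 2.2e-04.

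Among the falls, YHR022C (chromosome VIII from 149712 to 149771) fell by 1.15 on the log2 scale, with an adjusted p of 0.0087. VBA5 fell by 0.93 and VBA3 fell by 0.88, and these transporter genes are too alike for the copy to be certain. The phosphate transporter gene PHO89 fell by 0.87, the proline permease gene PUT4 fell by 0.79, YNR064C fell by 0.76, the stress-induced DDR2 fell by 0.60 and HAL9, a transcription factor gene of salt tolerance, fell by 0.56. YHR145C at -0.84 and YKL177W at -0.58 also passed but are annotated as dubious reading frames, so the transcript behind them is uncertain. The falls after YHR022C had adjusted p-values between 0.0111 and 0.049. With normexp background correction VBA5, VBA3, HAL9, YHR145C and YKL177W no longer passed, DDR2 did not with quantile normalization, and DDR2 and YKL177W did not with a trend on signal.

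**Figure D2:**
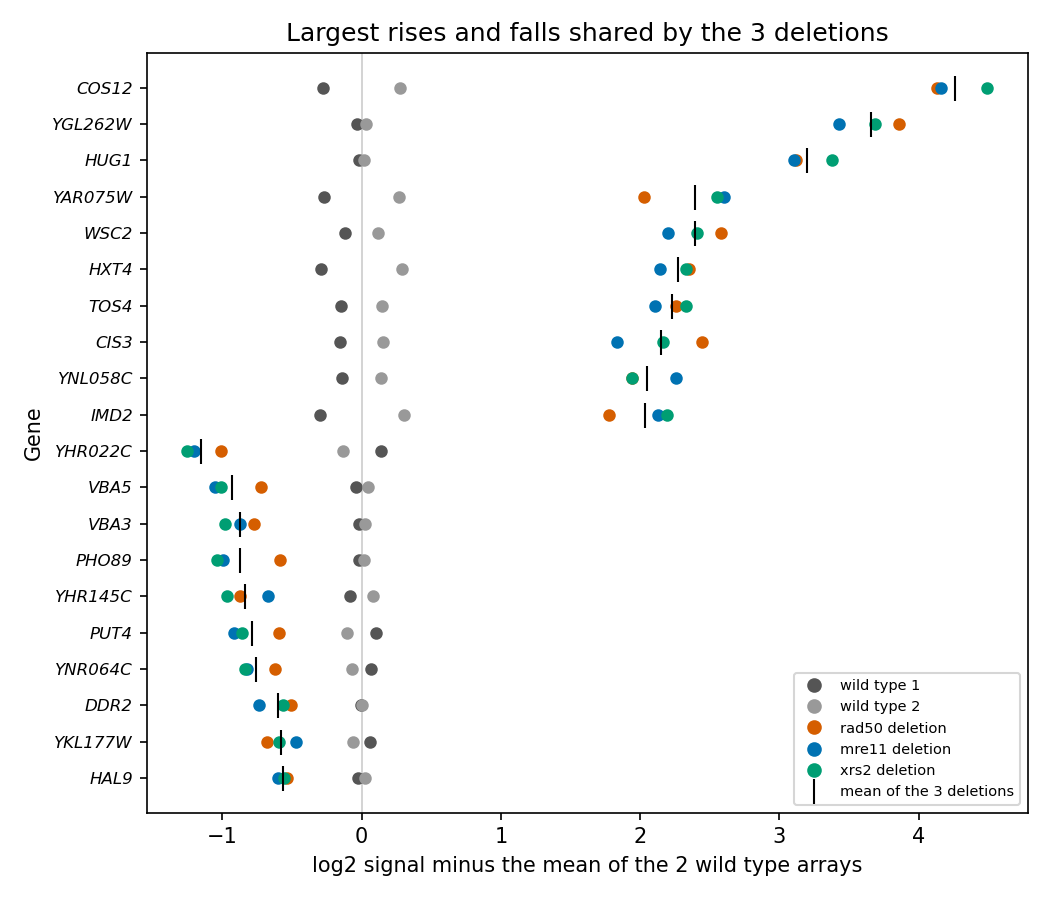
Log2 signal on each array minus the mean of the wild type arrays (x axis) for the 10 largest rises and 10 largest falls (y axis) that passed in the comparison of the 3 deletions with wild type. Points are arrays and bars are the means of the deletions, from 4.26 for COS12 to -1.15 for YHR022C.

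All 226 genes had every deletion array beyond both wild type arrays. Over all genes tested, 21.7% lay above and 18.6% below both wild type arrays in every deletion, where chance gives 10% in each direction. Dubious reading frames made up 20 of the 226. The count rested on the wild type pair, since without wild type replicate 1 it was 10 genes (all higher), without wild type replicate 2 it was 54 (52 higher, 2 lower) and without the rad50 deletion it was 145. Of the genes named for this comparison, here and in the gene lists below, COS12, YGL262W, HUG1, WSC2, HXT4, TOS4, YLR012C and DUN1 passed without wild type replicate 1. Without wild type replicate 2 those passed too, as did CIS3, YAR075W, YNL058C, IMD2, YHR022C, PLM2, SSA2, HXT1, HXT3, CYS3, CLN2, CDC45, CDC21 and CDC20. RNR1, CPR6, SSA4 and SAM1 no longer passed without the rad50 deletion, AAC3, RED1, SPL2, YHR145C and YKL177W without the rad50 or the xrs2 deletion, YNR064C without xrs2, SPO13, PHO89 and PUT4 without mre11 or xrs2, and DDR2, HAL9, EXO1 and HSP60 without any one of these.

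Of 34 genes of the G1/S transition and of DNA replication, 12 rose, or 20 adjusted over the list alone. Their median difference was 0.54, and examples are CLN2 at 1.54, the replication initiation gene CDC45 at 1.52, the thymidylate synthase gene CDC21 at 1.33 and POL30, for the sliding clamp PCNA, at 1.22. The list passed camera with an adjusted p of 2.2e-11, but not with an estimated correlation (adjusted p = 0.336 with an estimated correlation). Of 21 DNA damage-induced genes, 7 rose, or 10 adjusted over the list alone, with a median of 0.46 (0.30 without the xrs2 deletion, where the list still passed). Besides HUG1 these included the checkpoint kinase gene DUN1 at 1.90, RNR1 at 1.72 and PLM2 at 1.45. Camera gave an adjusted p of 4.9e-05 for them (adjusted p = 0.336 with an estimated correlation). Of 21 genes of G2/M and daughter cell separation, 4 rose, or 12 adjusted over the list alone, with a median of 0.42. They were the cyclin genes CLB2 at 1.34 and CLB1 at 1.24, CDC20 at 1.11, an activator of the anaphase-promoting complex, and HOF1 at 0.88. Camera gave an adjusted p of 1.1e-05 for this list (adjusted p = 0.368 with an estimated correlation). These 3 lists share 0 genes with each other. Their estimated correlations were 0.044, -0.025 and 0.036 in that order, against the preset 0.01. The DNA damage list thus lost its call at an estimate below the preset, so that loss is not a sign of its genes varying together.

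Of 26 heat shock protein genes, 4 rose, or 13 adjusted over the list alone, with a median of 0.38. They were the chaperone genes SSA2 at 1.32, CPR6 at 0.88, HSP60 at 0.70 and SSA4 at 0.69, and camera gave an adjusted p of 4.2e-09 (adjusted p = 0.537 with an estimated correlation). In methionine and sulfur metabolism 3 of 32 genes rose, both over all genes and adjusted over the list alone. CYS3 rose by 1.56, SAM1 by 1.18 and MET32 by 0.74, and the list had an adjusted p of 0.00266 (adjusted p = 0.537 with an estimated correlation). In the list of cell wall and anaerobic mannoproteins 3 of 26 rose, or 8 adjusted over the list alone. CIS3 and CRH1, at 1.23, act in the cell wall, while AAC3, at 0.88, encodes a mitochondrial carrier used without oxygen and no longer passed with normexp, quantile or cyclic loess processing. This list had an adjusted p of 0.0106 (adjusted p = 0.463 with an estimated correlation), which was 0.0513 with normexp background correction. Of 38 nuclear genes of oxidative phosphorylation 1 rose, the cytochrome c gene CYC1 at 0.96, also when adjusted over the list alone. The list median was 0.22 and its adjusted p 3.8e-05 (adjusted p = 0.602 with an estimated correlation), and without wild type replicate 1 the median was 0.14 and the list still passed.

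Further lists passed camera on small shifts with no gene past the threshold over all genes. The 137 cytosolic ribosomal protein genes had a median of 0.16, with 0 passing when adjusted over the list alone and an adjusted p of 0.0046 (adjusted p = 0.81 with an estimated correlation). Their median was -0.019 without wild type replicate 1 and 0.030 without the xrs2 deletion, and the list passed in neither case (adjusted p = 0.676 and 0.622), nor with normexp (0.0614). It was 0.35 without wild type replicate 2 and 0.29 without the mre11 deletion, where the list passed. The wild type arrays themselves differed by 0.35 in the size of this list's median (replicate 1 minus replicate 2, -0.35). The histidine and adenine genes had a median of 0.23, with 2 of 19 passing when adjusted over the list alone and an adjusted p of 0.0031 (adjusted p = 0.602 with an estimated correlation). The mitochondrially encoded genes had a median of 0.26, with 1 of 15 passing when adjusted over the list alone and an adjusted p of 0.0221 (adjusted p = 0.667 with an estimated correlation). Without the rad50 deletion their median was 0.14 and the list did not pass (adjusted p = 0.126). Glycolysis genes, at a median of 0.24, and TCA cycle genes, at 0.18, each had 0 passing when adjusted over the list alone and an adjusted p of 0.0336 (adjusted p = 0.602 with an estimated correlation). The glycolysis median was 0.0072 with quantile normalization (adjusted p = 0.242), and that list also failed with normexp, cyclic loess or a trend on signal, without wild type replicate 1 (median 0.17, adjusted p = 0.122) and without the rad50 deletion (0.23, adjusted p = 0.135). The TCA cycle list failed with normexp or cyclic loess, without wild type replicate 1 (0.10, adjusted p = 0.216) and without the mre11 deletion (0.18, adjusted p = 0.119). The 8 Y-prime helicase copies, which are near-identical and so uncertain one by one, had a median of 0.21, 0 passing when adjusted over the list alone and an adjusted p of 0.0341 (adjusted p = 0.694 with an estimated correlation). They failed with normexp, cyclic loess or a trend on signal, without wild type replicate 2 (0.11, adjusted p = 0.453), without the rad50 deletion (0.16, adjusted p = 0.135) and without the mre11 deletion (0.21, adjusted p = 0.0665).

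Lower lists were autophagy, stationary phase genes and the phosphate regulon. The 36 autophagy genes had a median of -0.17 and 0 past the threshold, also when adjusted over the list alone, with an adjusted p of 0.0047 (adjusted p = 0.694 with an estimated correlation). Their medians were -0.19, -0.049 and -0.32 in the rad50, mre11 and xrs2 deletions, and without xrs2 the list stood at -0.082 and did not pass (adjusted p = 0.0638). Of 27 stationary phase genes DDR2 fell, also when adjusted over the list alone, and the median was -0.20 with an adjusted p of 0.0106 (adjusted p = 0.602 with an estimated correlation). Without the xrs2 deletion it was -0.11 and the list did not pass (adjusted p = 0.0893). In the phosphate regulon 2 of 19 fell, PHO89 and SPL2 at -0.55, or 3 adjusted over the list alone, but SPL2 did not pass with quantile normalization, median centring or cyclic loess. The list's median was -0.12 and its adjusted p 0.0336 (adjusted p = 0.602 with an estimated correlation). It failed without the rad50 deletion (-0.024, adjusted p = 0.135), without wild type replicate 2 (-0.070, adjusted p = 0.0742), without the mre11 deletion (-0.10, adjusted p = 0.0509) and with quantile normalization (adjusted p = 0.074) or cyclic loess (adjusted p = 0.0629). In all 16 of 43 lists passed camera, 13 higher and 3 lower, and 10 passed fry, which does not compare a list with other genes. Those 10 include the list of the MRX complex (fry adjusted p = 7.2e-05), whose members are the deleted genes. With an estimated correlation 0 passed camera, while 4 had an unadjusted p under 0.05.

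Genes that act directly in double-strand break repair and its checkpoint did not shift as a list (adjusted p = 0.368). Of 29, the recombination genes RDH54 at 0.78, SRS2 at 0.75 and EXO1 at 0.69 rose, or 4 adjusted over the list alone. The list median of 0.046 turned to -0.057 under quantile normalization and to -0.012 under cyclic loess, and EXO1 passed with neither. Of 17 hexose transporter genes HXT4, HXT1 at 1.73 and HXT3 at 1.20 rose, and adjusted over the list alone 7 were higher and 1 lower, with a list p of 0.0606 after adjustment that was 0.00558 without wild type replicate 2 (median 0.30 against 0.20) and also passed with normexp, median centring and the authors' values. In other settings the list did not pass, and its median was 0.011 with quantile normalization, 0.052 with all 5 arrays above background, 0.090 with cyclic loess, 0.10 without wild type replicate 1 and 0.11 without the mre11 deletion. This list also passed between the wild type arrays (replicate 1 minus replicate 2, -0.10, adjusted p = 0.00128), so no shift of it is shown. Of 32 meiosis and sporulation genes DMC1 at 0.98, SPO13 at 0.87 (not past the threshold with normexp or median centring) and RED1 at 0.74 rose, and adjusted over the list alone 5 were higher and 1 lower. That list had an adjusted p of 0.122, or 0.0189 without the rad50 deletion (median 0.18), and its median of 0.13 turned to -0.065 under quantile normalization. Of 10 histone genes the linker histone gene HHO1 rose by 0.82, also when adjusted over the list alone. Telomere maintenance and silencing genes had 0 of 15 past the threshold, also when adjusted over the list alone, with a median of -0.14 and an adjusted p of 0.149. Of 75 ribosome biogenesis genes 0 passed either way. Their median of 0.0083 and camera's direction differed in sign, with an adjusted p of 0.627, and the median was -0.019 under quantile normalization and -0.010 under median centring. The list passed as lower without the xrs2 deletion (-0.18, adjusted p = 2.1e-04) and as higher without the mre11 deletion (0.20, adjusted p = 0.00135). Both are camera at the preset correlation. The estimated correlation of the list was 0.81, and with it camera over all 5 arrays gave an adjusted p of 0.962.

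Each single deletion was compared with wild type to ask what the loss of each subunit changed. In the rad50 deletion COS12 rose by 4.13, YGL262W by 3.86, HUG1 by 3.12, WSC2 by 2.58, CIS3 by 2.44 and HXT4 by 2.35. PUL3 fell by 1.43, FDH1, for formate dehydrogenase, fell by 1.30, CHA1, for the enzyme that degrades serine and threonine, fell by 1.22 and YGR067C fell by 1.16. The adjusted p-values of these genes lay between 7.2e-04 and 0.0216. YLR012C was at least 6.03-fold higher, with an adjusted p of 0.00165, and the dubious frame YIL025C was higher by at least 1.89 on the log2 scale, with an adjusted p of 0.00292. AAD3 was at least 2.44-fold lower, with an adjusted p of 0.0139, but its difference was 0.15 with normexp background correction. In all 230 genes passed, 189 higher and 41 lower, and 148 of them had passed in the same direction in the comparison of the 3 deletions together.

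In the mre11 deletion COS12 rose by 4.16, YGL262W by 3.43, YAR075W by 2.61, the arginine synthesis gene ARG1 by 2.54 and MIG2, for a glucose-responsive repressor, by 2.37, and HUG1 rose 8.59-fold. PUL3 fell by 1.90, the phosphate transporter gene PHO84 fell by 1.45, the repressor gene NRG2 fell by 1.44, CHA1 fell by 1.43, PDR12, for an exporter of weak acids, fell by 1.30 and YGR122W fell by 1.27. Adjusted p-values lay between 0.00137 and 0.0445. YLR012C was at least 5.12-fold higher, with an adjusted p of 0.00243. Bounds for the dubious frames YDR241W and YNL105W did not pass, with adjusted p-values of 0.0725 and 0.101, and YNL105W changed sign to 0.31 with normexp background correction. In all 304 genes passed, 254 higher and 50 lower, and 176 of them had passed in the same direction in the comparison of the 3 deletions together.

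In the xrs2 deletion COS12 rose by 4.49, YGL262W by 3.69, HUG1 by 3.38, YAR075W by 2.55, WSC2 by 2.41 and HXT4 by 2.33. SHH4, a relative of a succinate dehydrogenase subunit gene, fell by 1.37, YHR022C fell by 1.25 and LPX2 fell by 1.19. YLR161W fell by 1.26, YLR156W fell by 1.24 and YLR159W fell by 1.24, and these are near-identical copies, so which of them changed is uncertain. Adjusted p-values lay between 9.2e-04 and 0.0202. YLR012C was at least 5.70-fold higher, with an adjusted p of 0.00188. In all 424 genes passed, 342 higher and 82 lower, and 192 of them had passed in the same direction in the comparison of the 3 deletions together.

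These counts rest on the spread of a single wild type pair. With the spread of the other fit they were 59, 72 and 102 for the rad50, mre11 and xrs2 deletions, and with normexp background correction 1521, 1362 and 1336. Without a test, 88, 113 and 115 genes lay at least 2-fold beyond both wild type arrays. Without wild type replicate 2, 160, 220 and 231 lay at least 2-fold from replicate 1 alone, a looser rule that could not lower the counts.

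The single deletions were also compared for the genes they shared. Rises called in all 3 strains numbered 128, where 0.434 would be found if the calls were independent, and falls called in all 3 numbered 5, where 0.0044 would be. The strains share their wild type arrays, so their calls are not independent, and the simulated counts below are for pairs only. The rad50 and mre11 deletions shared 136 rises, the rad50 and xrs2 deletions 148 and the mre11 and xrs2 deletions 175, and the shared falls of these pairs numbered 11, 10 and 9. The log2 differences of rad50 and mre11 correlated across genes with r = 0.567 (rho = 0.493), those of rad50 and xrs2 with r = 0.671 (rho = 0.647) and those of mre11 and xrs2 with r = 0.578 (rho = 0.498). Simulations in which only the shared wild type arrays linked the strains gave a mean r of 0.333, 0.336 and 0.335, and at most 9, 9 and 11 shared calls in either direction. The covariance in them was 0.0075, 0.0076 and 0.0076, against 0.084, 0.105 and 0.094 in the data. The simulated r is therefore not the part of the observed r that the controls give. The simulated differences also had a far smaller spread over genes than those in the data, as the small covariance at such an r shows. Their shared counts are therefore no baseline for strains with 230, 304 and 424 calls. The shared rises were above the highest simulated counts. The shared falls were little above them or, for mre11 and xrs2, below. Neither comparison shows how many shared calls the controls alone would give. Independent calls would share 0.33, 0.55 and 0.67 falls in the same pairs. Part of these correlations comes from the shared controls, and with a different wild type array for each strain r was 0.486 and 0.408, 0.614 and 0.491, and 0.489 and 0.448 for the same pairs. Genes are not independent replicates, so no p is given.

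The deletions were compared with each other to ask whether the loss of different subunits changed different genes. Ribosome biogenesis genes had a median of 0.042 in the rad50 deletion, -0.39 in the mre11 deletion and 0.34 in the xrs2 deletion. Cytosolic ribosomal protein genes had medians of 0.17, -0.083 and 0.42 in that order. Glyoxylate cycle and gluconeogenesis genes stood at -0.15, 0.35 and -0.31, and peroxisomal fatty acid oxidation genes at -0.23, 0.32 and -0.33. Arginine biosynthesis genes stood at 0.10, 0.69 and 0.19. The wild type arrays differed from each other (replicate 1 minus replicate 2) by -0.17 for ribosome biogenesis, -0.35 for ribosomal proteins, -0.11 for the glyoxylate cycle, -0.14 for peroxisomal oxidation and 0.031 for arginine. With 1 array per strain these differences between strains were not shown to exceed those between samples of 1 strain, since camera on plain log2 differences passed 3 of 43 lists between the wild type arrays, against 7 between rad50 and mre11, 6 between rad50 and xrs2 and 9 between mre11 and xrs2. The lowest adjusted p was 6.1e-24 between the wild type arrays and 2.1e-15, 1.7e-07 and 1.4e-36 between the strains in that order. In the 3 deletions together 0 genes of the glyoxylate, peroxisomal and arginine lists passed, over all genes or adjusted over the list alone, with list p-values of 0.31, 0.266 and 0.112 after adjustment. These calls turned on single arrays, since without the mre11 deletion the glyoxylate list passed at -0.26 (adjusted p = 5.2e-04) and the peroxisomal list at -0.26 (adjusted p = 6.6e-05), and the arginine list passed without rad50 at 0.37 (adjusted p = 0.0189) and without xrs2 at 0.38 (adjusted p = 0.0367). All of these are camera at the preset correlation. With an estimated correlation camera over all 5 arrays gave the 3 lists adjusted p-values of 0.844, 0.82 and 0.803.

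**Figure D3:**
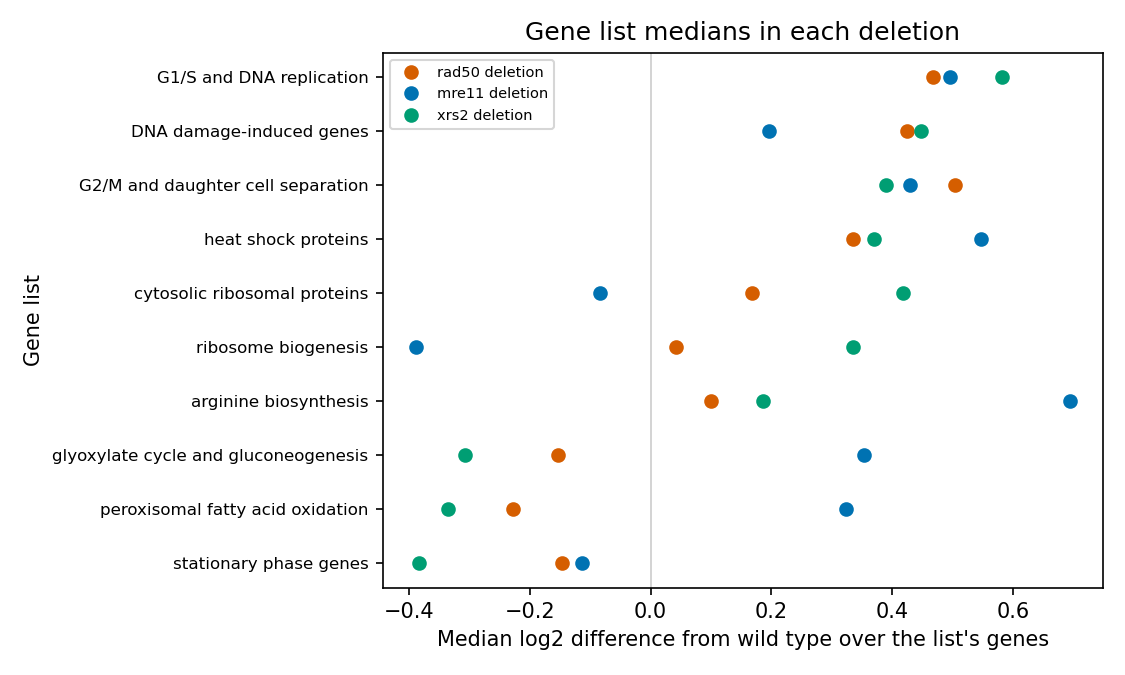
Median log2 difference from wild type over the genes of a list (x axis) for 10 gene lists (y axis), with 1 point per deletion. The G1/S list lies between 0.47 and 0.58 in the 3 deletions, while the ribosome biogenesis list runs from -0.39 in the mre11 deletion to 0.34 in the xrs2 deletion.

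Single genes were also compared between strains. Their p-values take the spread from the wild type pair alone, so each value describes 1 sample per strain and a passing gene is not shown to differ between the strains. ARG1 was higher in the mre11 deletion than in the rad50 deletion by 2.32 (difference of rad50 minus mre11 -2.32, adjusted p = 0.0202) and than in the xrs2 deletion by 2.04. ARG3 had a difference of -2.08 between rad50 and mre11, with an adjusted p of 0.0466, and of 1.87 between mre11 and xrs2. Between mre11 and xrs2, MTC7 differed by 1.80, PDR12 by -2.44, YOL014W by -2.26 and PMA1, for the plasma membrane proton pump, by -2.18, each with an adjusted p of 0.0474, as for ARG1 and ARG3 there. YIL025C, a dubious frame that was above background only in the rad50 deletion, was higher there by at least 1.57 on the log2 scale than in the mre11 deletion and by at least 2.04 than in the xrs2 deletion. Besides the deleted genes, 3 genes passed between rad50 and mre11, 1 between rad50 and xrs2 and 29 between mre11 and xrs2, while 926, 767 and 1115 genes had an unadjusted p under 0.05. Among the 29, ECM23 and YEL010W were dim in the mre11 deletion. Their bounds for xrs2 over mre11, at least -0.075 and -0.11 on the log2 scale, lie below 0 and leave the difference undetermined. These genes were singled out after their values were seen. The calls between mre11 and xrs2 fell from 31 genes in all to 2 with quantile normalization, median centring, no background filter, the authors' table or the brightest probe, where none of the genes given a value above for that pair passed, and to 0 with the spread of the other fit. Between rad50 and mre11 ARG3 no longer passed with quantile normalization, median centring, no background filter or the brightest probe, while ARG1 passed with each. There the calls went from 5 to 240 with normexp background correction and to 0 with the spread of the other fit, and between rad50 and xrs2 from 3 to 786 and 0.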

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

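The tests of a growing share of cells, of a general rise of amino acid genes and of lists between the wild type arrays were chosen after the results were seen. The values below are log2 differences of the first strain minus the second, each from 1 array per strain, that passed limma (single genes) or camera at the preset correlation (list medians). Passing does not establish a difference between the strains, for a gene because the spread comes from the wild type pair alone, or for a list because camera on plain log2 differences passed 3 of 43 lists between the wild type arrays, among them cytosolic ribosomal proteins at -0.35 (adjusted p = 6.1e-24) and ribosome biogenesis at -0.17 (adjusted p = 0.00244). That same test passed 7 lists between rad50 and mre11, 6 between rad50 and xrs2 and 9 between mre11 and xrs2. The list differences were larger in size than between the wild type arrays for 8 of 9 lists between rad50 and mre11, 7 of 8 between rad50 and xrs2 and 11 of 11 between mre11 and xrs2, and the exceptions were both ribosomal proteins.

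In the rad50, mre11 and xrs2 deletions 9, 8 and 16 of 34 G1/S genes, 7, 8 and 8 of 21 DNA damage-induced genes and 5, 4 and 6 of 21 G2/M genes were called higher (lists over the 3 deletions with adjusted p = 0.336, 0.336 and 0.368 with an estimated correlation), while ribosome biogenesis differed by 0.39 between rad50 and mre11, -0.32 between rad50 and xrs2 and -0.70 between mre11 and xrs2. A larger share of growing cells would raise ribosome biogenesis genes. In the mre11 sample they were lower instead (-0.39, interval over genes from -0.43 to -0.28), against a difference of 0.17 in size between the wild type arrays. These intervals are over genes of 1 array, not over samples, and the genes had an estimated correlation of 0.81. The test therefore does not decide the question for the mre11 deletion. In the xrs2 sample ribosome biogenesis genes were higher (0.34, interval from 0.29 to 0.39), as a larger share would give. The same limits leave the question undecided there too. In the rad50 deletion (0.042, interval from -0.017 to 0.091) a larger share cannot be told apart from no such share because the interval holds 0. The G1/S medians spanned a narrower range, at 0.47, 0.50 and 0.58 in the rad50, mre11 and xrs2 deletions. A trend with signal level between arrays is argued against as the whole cause, since after cyclic loess the G1/S median was 0.49 (interval from 0.28 to 0.67). Loss of the complex itself stays open and was not tested apart from other differences between the cultures.

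Arginine biosynthesis genes were higher in the mre11 sample, with list differences of -0.82 between rad50 and mre11 and 0.56 between mre11 and xrs2. ARG1 differed by -2.32 and 2.04 and ARG3 by -2.08 and 1.87 for the same pairs, and of these only the ARG1 difference between rad50 and mre11 passed with quantile normalization. A general rise of amino acid genes cannot be told apart. The highest median among 4 other amino acid lists in that strain was 0.20. The intervals over genes of these 4 lists spanned a range from -0.16 to 0.39, which is not the interval of 1 list. That range reached past 0.347, the level that the test took from the arginine median itself. Weaker signalling by arginine through its regulator, which would lower the arginine-degrading enzymes, also cannot be told apart, because CAR1 differed by -0.084 and CAR2 by 0.093, neither clearly lower nor both higher. With 1 array of that strain, loss of MRE11 and a difference of its culture both stay open, untested.

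Cytosolic ribosomal protein genes differed by 0.26 between rad50 and mre11, -0.25 between rad50 and xrs2 and -0.50 between mre11 and xrs2. Glyoxylate cycle and gluconeogenesis genes differed by -0.37 between rad50 and mre11 and 0.51 between mre11 and xrs2, and peroxisomal fatty acid oxidation genes by -0.56 and 0.56. Proteasome genes differed by -0.12 and 0.14 for those same pairs. Between mre11 and xrs2, oxidative stress defence genes differed by 0.19 and histidine and adenine genes by -0.22. Between rad50 and xrs2, mitochondrially encoded genes differed by 0.29. Between rad50 and mre11, meiosis and sporulation genes differed by -0.12. Stationary phase genes differed by 0.22 between rad50 and xrs2 and by 0.37 between mre11 and xrs2, autophagy genes by 0.14 and 0.25, and the iron regulon by -0.17 and -0.15. Thiamine metabolism differed by 0.31 between rad50 and mre11 and by 0.21 between rad50 and xrs2, and the zinc regulon by 0.13 and 0.17. On plain log2 differences proteasome genes did not pass for either pair (adjusted p = 0.219 and 0.111), nor did histidine and adenine genes between mre11 and xrs2 (0.0737), meiosis genes between rad50 and mre11 (0.0551), or autophagy (0.114) and thiamine genes (0.162) between rad50 and xrs2. Between the mre11 and xrs2 samples MTC7 had a difference of 1.80, PDR12 of -2.44, PMA1 of -2.18 and YOL014W of -2.26, and none of these passed with quantile normalization, median centring, no background filter, the authors' table, the brightest probe or the spread of the other fit. YIL025C, a dubious frame dim on the other arrays, had fitted differences of 2.83 between rad50 and mre11 and 2.59 between rad50 and xrs2, which are taken against signals at background, and only the bounds of at least 1.57 and at least 2.04 hold.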

How the results depend on the processing

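Cyclic loess and the count without dubious frames were chosen after the data were seen, and the other alternatives before. Of the values for named genes in the 3 deletions together, 985 kept their direction and side of the threshold, 131 no longer passed, 11 newly passed and 1 reversed. For single deletions these were 468, 10, 4 and 2, and for pairs of strains 38 kept and 34 no longer passed. The 468 include 45 values without wild type replicate 1 and 45 without replicate 2. For those only the direction was checked, because they were not set against the threshold. Most of these genes were chosen for lying beyond both wild type arrays by at least 1, so their direction could not reverse. Their values without a wild type array are thus no test of the result. For list medians they were 308, 43, 10 and 14. The cause was not tested for the changes below unless given. No paired analysis was possible because replicate numbers exist only in the wild type labels.

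For the 3 deletions together, 226 genes became 542 in the 4-group fit, whose spread leaves out differences between strains, 419 at an adjusted p under 0.1 and 93 with a 2-fold minimum. Leaving out 1 array gave 10 to 219 genes, where a lone wild type array was assumed to vary like the deletions. All 10 genes left without wild type replicate 1 were among the 226. With normexp background correction 185 of 217 calls were among the 226, with quantile normalization 176 of 191, with cyclic loess 202 of 224 and 204 of 206 with the authors' values. The 16 lists became 0 with an estimated correlation.

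For the rad50, mre11 and xrs2 deletions against wild type (230, 304 and 424 genes), normexp gave 1521, 1362 and 1336 (813 higher and 523 lower in xrs2), quantile normalization 148, 177 and 230, all 5 arrays above background 487, 637 and 965, and a spread with a trend on signal 641, 980 and 1373. The spread of the 2-group fit gave 59, 72 and 102, and a 2-fold minimum with no test 88, 113 and 115. Cyclic loess gave 383 for rad50 and 647 for xrs2 (454 higher, 193 lower). Median centring gave 140 and no background filter 150 for rad50, and the authors' values 275 for xrs2. Leaving out a wild type array gave 123 to 160, 140 to 220 and 148 to 231 genes past the 2-fold minimum from the remaining wild type array. That rule is looser than the minimum beyond both arrays and could not lower the counts.

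Between rad50 and mre11, 5 genes became 240 with normexp (134 higher, 106 lower), 98 with all 5 arrays above background, 12 with the authors' table (9 higher, 3 lower), 291 with a trend, 47 with cyclic loess, 0 with the spread of the 2-group fit and 100 at 2-fold with no test. Between rad50 and xrs2, 3 became 786 (662 higher, 124 lower), 20, 17, 170, 11, 0 and 60 in that order, and 5 with quantile normalization. Between mre11 and xrs2, 31 became 741 with normexp, 290 with all 5 arrays above background, 652 with a trend, 113 with cyclic loess, 0 with the spread of the 2-group fit and 116 at 2-fold with no test. There it was 2 with each of quantile normalization, median centring, no background filter, the authors' table and the brightest probe.

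With a different wild type array for each strain, r was 0.486 and 0.408 for rad50 and mre11, 0.614 and 0.491 for rad50 and xrs2, and 0.489 and 0.448 for mre11 and xrs2. For rad50 and mre11 it was 0.646 with normexp, 0.640 with all 5 arrays above background and 0.503 with the authors' table, and for rad50 and xrs2 0.746 and 0.583 with the latter alternatives.

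Medians that changed sign were those of ribosomal proteins (-0.019 to 0.35 when leaving out 1 array), double-strand break repair (-0.057 with quantile normalization, -0.012 with cyclic loess, -0.013 to 0.081 leaving out 1 array), glyoxylate cycle (-0.26 to 0.073), peroxisomal oxidation (-0.26 to 0.041), meiosis (-0.065 with quantile normalization) and ribosome biogenesis (-0.019 with quantile normalization, -0.010 with median centring, -0.18 to 0.20 leaving out 1 array). With normexp YNL105W in the mre11 deletion was 0.31, AAD3 in the rad50 deletion 0.15 and RIF2 in the 3 deletions 0.13. Signal over background limits dim genes most in the rad50 deletion, where 419 genes were not well above background against 82 to 258 on the other arrays.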

Other observations

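The lists of tubulins, spindle pole body, cell wall glucan and N-glycosylation genes were chosen after the called genes were seen, and the tests of COS12 and of splits before their results. All 4 tubulin genes, TUB1, TUB2, TUB3 and TUB4, rose in the 3 deletions, with a median of 0.93 (one-sided Fisher's exact test, adjusted p = 4.1e-06). Of 18 genes for cell wall glucan enzymes 7 rose (CRH1, EXG2, GAS3, GAS5, SCW10, SCW4 and SIM1), with an adjusted p of 4.1e-06. Of 12 spindle pole body and kinetochore SPC genes SPC24, SPC29 and SPC97 rose, and of 12 ALG genes of protein N-glycosylation ALG14, ALG5 and ALG7 rose, each with an adjusted p of 0.0106. Since these lists were built from genes already seen to rise, the p-values are not independent evidence.

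Among lists fixed before the data were examined, 2 of 25 ergosterol genes rose, ERG4 by 1.23 and ERG6 by 0.76, and 2 of 16 genes of the unfolded protein response, ERO1 by 0.90 and the chaperone gene KAR2 by 0.83. Neither list passed camera, with adjusted p-values of 0.103 and 0.112, though the unfolded protein response list passed fry (adjusted p = 0.0048). The mating type a genes were above background on all arrays. So were STE3 at -1.32 and -1.37 in the wild type arrays, SAG1 at -2.18 and -2.24, MF(ALPHA)1 at -3.75 and -3.81 and MF(ALPHA)2 at -6.41 and -6.47, which cells of the opposite mating type express most.

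COS12 and YGL262W, neighbours at the left end of chromosome VII, were higher in all 3 deletions. A like rise of the last 10 measured genes of each chromosome end is argued against as the whole cause. These 318 genes lay above the others by a median of only 0.16 (interval from 0.13 to 0.19), with 14 called higher and 4 lower. A rise limited to the outermost genes would be diluted in that median, so the test cannot decide on it. A change of like size that reaches the next genes is argued against by PAU11, YGL260W and YPS5, whose highest difference in any deletion was 0.68. In the rad50, mre11 and xrs2 deletions PAU11 stood at -0.086, 0.36 and 0.077 and YPS5 at 0.17, 0.45 and 0.68. YGL260W was dim in the rad50 deletion. A smaller change of these genes stays open. Cross-hybridisation with other COS genes is argued against by their median of 0.10 (interval from -0.19 to 0.13) and highest value of 0.22 over 11 genes. A change limited to these genes that comes with loss of the complex may remain as a hypothesis, and a variant shared by the deletion strains was not tested.

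Of the 10 splits of the 5 arrays into 3 and 2, only 1, the real one, gave as many as 226 genes, and the highest of the others gave 0. So few splits are too few for a share under 0.05.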
